A study of Mus musculus with 9 samples.

How the data were processed

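Transcript levels were measured in splenic follicular B cells of mice aged 6 to 12 weeks on 9 single-colour arrays, 3 for each of 3 heavy chain genotypes. Per the labels' protocols, RNA was extracted with TRIzol, 54 to 360 ng of total RNA was amplified with a Nugen PicoWTA kit, 3 µg of the cDNA went through an exon module and 2.5 µg was labelled with biotin. A value belongs to a probe set and not to a whole gene. The submitters' processing notes name R version 3.3.1. The deposited table holds log2 signals of 41345 probe sets as the authors processed them. The background correction, the normalization and the summary of probes into probe sets are not given in the sources used here. The log2 scale was read from the values: the arrays' medians lay between 3.53 and 3.69, their distributions were alike without being identical, and 0 pairs of arrays held identical values. Scanner files were not analysed here. For arrays, their number limits the precision.

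Probe sets were named from the platform's gene annotation. It paired 23521 probe sets with 1 gene symbol and 1814 with several, and left 16010 without a gene here. No gene was named from a probe set with several symbols. The gene identifiers of 23328 of the probe sets with 1 symbol were found in a mouse gene table of the GRCm38.p6 assembly, which was used for gene kinds and for which genes lie inside another, with no coordinates taken from it. The named probe sets covered 22180 genes, of which 1082 had more than 1 probe set. The brightest probe set over the 9 arrays stood for each gene. A gene was tested when its signal lay above the median of all probe sets of the array on at least 3 of the 9 arrays. This left 12170 genes and set aside 10010.

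All 9 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with 1 mean per genotype, no covariate, a variance shared over the 3 genotypes with 6 residual degrees of freedom, and moderation by eBayes. The contrasts were ε/ε minus wild-type, γ1/γ1 minus wild-type and ε/ε minus γ1/γ1, and a moderated F test asked for any difference among the genotypes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene passed at an adjusted p under 0.05. Every adjusted p in the text comes from limma unless another test is named. Of the 35 gene lists, the 31 with at least 3 genes tested entered limma's camera test with its preset correlation of 0.01, adjusted over the lists. The camera test with an estimated correlation and limma's fry test were run beside it. Correlations over genes are descriptions, since genes are not independent replicates. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

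The groups, contrasts, filter, gene lists, rule for named genes and alternatives were chosen before the data were examined, except where the text says otherwise. For each contrast the rule named the 10 genes with the highest and the 10 with the lowest log2 fold change among those that passed and whose 3 values in 1 group all lay above the 3 of the other. If fewer than 20 qualified, the 20 with the smallest p were named, as values where they missed the threshold. It always named Ighm, Ighd, Ighg1, Ighe, Cd79a and Cd79b. For each list described it named up to 4 members that passed with the largest absolute log2 fold change, or else the 2 with the smallest p, as values. No probe set carried the single symbol Ighd, Ighg1 or Ighe, so these have no value here.

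The alternatives were quantile normalization of the deposited values, arrays centred on their medians, no filter, a filter at percentile 75, the mean of a gene's probe sets, a trended and robust variance, array weights, a fit of only the 6 arrays compared, the replicate number as a block, each array left out in turn, an absolute log2 fold change of at least 1, an adjusted p under 0.1, and the other list tests. A covariate for the 2 arrays with low Xist, a fit of the 7 arrays with high Xist and a fit of protein-coding genes were added after the data had been seen. Chance values shared through the wild-type arrays were simulated with 100 draws of unchanged groups. A simulation with γ1/γ1 unchanged and ε/ε changed, also of 100 draws, was added after the data had been seen.

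The scripts were tested on data simulated for the 12170 genes. Of 100 genes changed by 1 on the log2 scale, 77 were recovered for ε/ε against wild-type, 81 for γ1/γ1 against wild-type and 78 for ε/ε against γ1/γ1. Of 100 genes changed by 2, 99, 100 and 98 were recovered in the same order. False calls numbered 6 of 182, 7 of 188 and 7 of 183 calls. With no gene changed, 0 genes and 0 lists passed in each of the 3 simulated comparisons. A list of 49 genes that was moved was found in each. These simulations drew genes independently and with the same variance in each genotype. They therefore do not test how correlation among genes bears on the list calls.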

Results

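Follicular B cells, the recirculating naive B cells of the spleen, were compared between mice homozygous for a heavy chain allele named after ε (the constant region of IgE), mice homozygous for an allele named after γ1 (the constant region of IgG1), and mice with the wild-type locus. The series concerns how the isotype of the heavy chain, and the dose of B cell receptor that goes with it, bears on the fate of B cells. All 9 genotype labels also carry VJk5, which they do not explain, and they do not say how the alleles were built. Each genotype had 3 arrays, and each array gave log2 signals for 41345 probe sets. The design calls the replicates independent without saying that they are separate animals, so the p-values measure the spread between these samples.

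The ε/ε arrays stood apart from the other 6 on the first principal component, which held 39.1% of the variance. There they lay between 22.1 and 44.2 and the other arrays between -25.1 and -9.0. Over the 12170 genes tested, Pearson's r between arrays of 1 genotype was 0.929 to 0.958 for ε/ε, 0.948 to 0.968 for γ1/γ1 and 0.970 to 0.978 for wild-type, and the ε/ε pair without replicate 1 had 0.958. Between genotypes r reached 0.951 for ε/ε with wild-type and 0.953 for ε/ε with γ1/γ1, above the lowest r within ε/ε. For γ1/γ1 with wild-type r reached 0.975, above the highest r within γ1/γ1. Xist, the RNA that silences 1 X chromosome in females, read 5.25 in ε/ε replicate 1 and 4.53 in γ1/γ1 replicate 1 against 10.37 to 10.79 elsewhere. Eif2s3y, a gene of the Y chromosome, read 7.40 and 7.99 in these arrays and 2.75 to 5.40 in the others. Kdm5d and Uty, also of the Y chromosome, read 5.90 and 5.08 in this ε/ε array and 6.08 and 6.52 in this γ1/γ1 array. Elsewhere they read at most 4.50 and 3.61, in ε/ε replicates 3 and 2, and the Eif2s3y reading of 5.40 was in ε/ε replicate 2. On the γ1/γ1 and wild-type arrays of high Xist, Eif2s3y, Kdm5d and Uty read at most 3.52, 3.09 and 2.97. The labels give no sex, but low Xist with high Y chromosome genes is the pattern of male samples. No wild-type array showed it, so sex appears unbalanced across genotypes. On the second principal component (14.2% of the variance) the arrays of low Xist lay at 23.0 and 22.8 and the others between -21.8 and 2.2. By limma's F test, 500 genes differed among the genotypes. That count was 231 without ε/ε replicate 1, 302 without ε/ε replicate 3, 324 without γ1/γ1 replicate 2, 293 without wild-type replicate 1, 181 without wild-type replicate 2, 173 without wild-type replicate 3 and 190 with only the 7 arrays of high Xist.

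The signal of Ighm, the gene of the μ constant region of IgM, depended on the probe set. Probe set 17284349 read 10.77 ± 0.21 (SD, n = 3) in wild-type cells, 4.44 ± 0.15 in ε/ε cells and 3.95 ± 0.98 in γ1/γ1 cells. It was lower in ε/ε (limma adjusted p = 0.000669 over all probe sets) and in γ1/γ1 (adjusted p = 0.00154). The mutant readings lie near the array medians of 3.53 to 3.69, so no fold is given, and background lessens any difference from a mean below those medians. The brightest Ighm probe set, 17284360, which stood for the gene, read 11.37 ± 0.17 in wild-type, 10.98 ± 0.06 in ε/ε and 9.41 ± 0.54 in γ1/γ1 cells. In the fit of genes it fell by 1.96 (SE 0.24, 3.88-fold lower, adjusted p = 0.0196) in γ1/γ1, and the ε/ε difference was -0.38 (SE 0.24, adjusted p = 0.346). The mean of its probe sets was lower in ε/ε by 2.06 (adjusted p = 0.000488, range over the alternatives 0.000488 to 0.623). Ighm was higher by 1.57 in ε/ε than in γ1/γ1 (SE 0.24, adjusted p = 0.00990), while the mean of its probe sets gave -0.27 with an adjusted p of 0.392, in a range of 0.00619 to 0.392 over the alternatives. Of the 7 probe sets named Ighm alone, 3 were lower in ε/ε than in wild-type and 1 was lower in γ1/γ1 at an adjusted p under 0.05 over all probe sets. Between ε/ε and γ1/γ1 1 was higher and 1 lower in ε/ε, the latter probe set 17284503 by 1.69 (adjusted p = 0.0247). Probe set 17284349 read 10.62 to 11.01 on the wild-type arrays and 3.07 to 5.01 on the mutant arrays, so it told mutant from wild-type labels. It did not tell ε/ε from γ1/γ1 (limma adjusted p = 0.573 over all probe sets). Which of the probe sets lie in a part of the locus that was replaced is not given, so they do not check which allele was carried.

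Cd79a and Cd79b encode the paired signalling chains of the B cell receptor. Cd79a read 10.11 ± 0.10 in ε/ε, 9.30 ± 0.38 in γ1/γ1 and 9.04 ± 0.62 in wild-type cells, a difference of 1.07 (SE 0.29, adjusted p = 0.0568) between ε/ε and wild-type and of 0.26 (adjusted p = 0.886) between γ1/γ1 and wild-type. Cd79b differed by 0.25 (adjusted p = 0.325) and 0.06 (adjusted p = 0.954). Without wild-type replicate 1, the Cd79a difference between ε/ε and wild-type was 1.37 with an adjusted p of 0.0296, in a range of 0.0296 to 0.172 over the alternatives. Between ε/ε and γ1/γ1 the difference was 0.81 for Cd79a (adjusted p = 0.163) and 0.19 for Cd79b (adjusted p = 0.509).

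**Figure D1:**
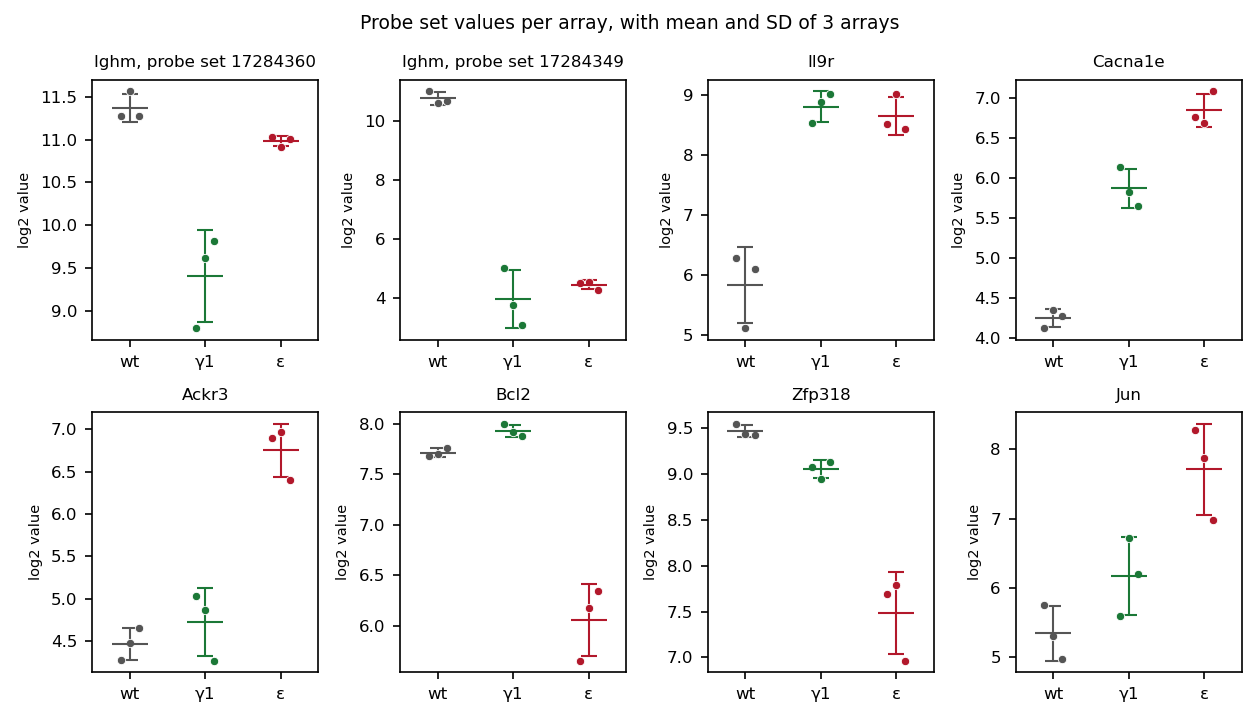
Log2 signal on each array (points) with the mean and SD of 3 arrays per genotype, for Ighm probe sets 17284360 and 17284349, Il9r, Cacna1e, Ackr3, Bcl2, Zfp318 and Jun. Il9r averaged 5.84 in wild-type and 8.81 and 8.66 in γ1/γ1 and ε/ε cells, while Bcl2 averaged 7.71 in wild-type and 6.06 in ε/ε cells.

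In ε/ε cells, set against wild-type to ask what the ε allele changes, Jun, of the AP-1 transcription factor, rose and the survival gene Bcl2 fell. Jun, a subunit of AP-1, rose from 5.34 ± 0.39 to 7.71 ± 0.66 (SD, n = 3), a change of 2.37 (SE 0.37, adjusted p = 0.00745) or 5.16-fold. Bcl2, which blocks mitochondrial apoptosis, fell by 1.66 (SE 0.18, adjusted p = 0.00152) from 7.71 ± 0.04 to 6.06 ± 0.36, or 3.15-fold. Zfp318, which B cells need to make IgD by reading through from Ighm, fell by 1.98 (SE 0.20, adjusted p = 0.00150) from 9.47 ± 0.07 to 7.48 ± 0.45. Il9r, the receptor of interleukin 9, rose by 2.82 (SE 0.30, adjusted p = 0.00152) from 5.84 ± 0.63 to 8.66 ± 0.32, and Cacna1e, a pore subunit of a voltage-gated calcium channel, by 2.60 (SE 0.17, adjusted p = 0.000101) from 4.25 ± 0.12 to 6.85 ± 0.21.

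In limma, 772 of the 12170 genes passed between ε/ε and wild-type, 283 higher and 489 lower in ε/ε, and 347 of them differed at least 2-fold (155 higher, 192 lower). The 3 arrays of 1 genotype all lay above those of the other for 771 of the 772 genes, and for 28.4% of all genes tested, where chance gives 10%. Under quantile normalization 710 genes passed, 410 higher and 300 lower. The share of higher calls was 57.7% in place of 36.7%, with 583 genes shared. The count was 424 with the 6 arrays compared, where 12 of the 54 named genes missed the threshold, 512 without wild-type replicate 1, 186 without wild-type replicate 2 and 210 without wild-type replicate 3. It was 525 without ε/ε replicate 1, 438 of them among the 772. Of the 54 genes named by the rule that passed, 27 passed with each array left out, among them Jun, Bcl2, Zfp318, Il9r and Cacna1e. The named genes that missed the threshold numbered 26 without wild-type replicate 2, 23 without wild-type replicate 3, 6 without wild-type replicate 1, 8, 9 and 10 without ε/ε replicates 1, 2 and 3, and 1, 6 and 5 without γ1/γ1 replicates 1, 2 and 3.

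Small RNAs and olfactory receptor genes were among those at the extremes of this contrast. Olfr310, an olfactory receptor gene, rose from 4.78 to 8.95, and the microRNA genes Mir297a-4, Mir466b-2 and Mir466h rose from 4.43 to 8.36, from 4.23 to 7.60 and from 7.56 to 10.84. Levels are given here, since many lie near the array medians, where background lowers a fold. These microRNAs have near-identical copies, so which copy was measured is uncertain. Among genes with known roles in lymphocytes, Rgs1, a brake on signalling by G protein-coupled receptors, rose from 3.38 to 5.90 (SE 0.42, adjusted p = 0.00997). Fabp5, a fatty acid carrier, rose from 4.20 to 6.58 (SE 0.37, adjusted p = 0.00745). H2-Q10, a class I gene with close relatives, rose to 6.09 from a mean below the wild-type array medians (adjusted p = 0.0191) and I830077J02Rik rose from 3.12 to 6.18 (adjusted p = 0.00106). At the other end Mir505 fell from 7.56 to 2.90 (SE 0.27, adjusted p = 5.07e-05), Cldn34b3, a claudin gene, fell from 6.55 to 2.34, Dennd5b, which activates Rab GTPases, fell from 7.22 to 4.25 (adjusted p = 0.00152) and Mir103-2 fell by 2.78 to 6.22. With the mean of probe sets the changes were 1.42 in place of 2.38 for Fabp5 and 1.32 for H2-Q10. H2-Q10 missed the threshold without ε/ε replicate 1 or wild-type replicate 2 or 3 (adjusted p up to 0.0811), and Mir103-2 without wild-type replicate 2 or 3 (up to 0.0557). The remaining 6, Mir5104, Snora69, Gm12657, AI504432, Olfr1219 and Snord87, fell from means of 5.54 to 7.69 to means of 3.12 to 5.27. Mir5104, Snora69 and Snord87 missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0664, 0.0687 and 0.0557), and Gm12657 without wild-type replicate 2 (0.0579).

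Immediate-early genes, which lymphocytes switch on within minutes of receptor engagement, were higher as a group in ε/ε cells. Of 29 tested, 10 rose and 0 fell over all genes, and 13 rose and 1 fell adjusted over the list alone. Their median difference was 0.57 (camera adjusted p = 3.89e-07, adjusted p = 0.496 with an estimated correlation, range over the alternatives 6.39e-09 to 0.496). Junb and Fos, further AP-1 subunits, rose by 1.77 (SE 0.34, adjusted p = 0.0176) and 1.67 (SE 0.43, adjusted p = 0.0479), and Dusp1, a phosphatase that turns off MAP kinases, by 1.68 (SE 0.25, adjusted p = 0.00607). Junb missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0811), and Fos without any of the arrays but γ1/γ1 replicate 1 (up to 0.156). Of the Egr and Nr4a genes on the list, singled out after their values were seen as direct targets of receptor signals, 0 of 5 rose, with differences of -0.76 to 0.99. Without ε/ε replicate 1 the difference was 0.37 (camera adjusted p = 1.92e-05), and under the stricter filter 0.91. The list median was 1.02, 0.35 and 0.57 in ε/ε replicates 1, 2 and 3, and replicate 1 also had the highest macrophage genes, at a list median of 2.16 over the wild-type means.

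Targets of NF-κB, the transcription factor family downstream of the receptor and of CD40 and BAFF, moved with them. Of 24 tested, 5 rose and 2 fell over all genes, and 13 rose and 3 fell adjusted over the list alone, with a median of 0.55 (camera adjusted p = 0.00544, adjusted p = 0.496 with an estimated correlation, range 0.000850 to 0.496). Traf1, an adaptor of TNF receptors, rose 2.83-fold (SE of the log2 change 0.20, adjusted p = 0.00404), and Nfkb2, the precursor of p52, by 1.38 (SE 0.22, adjusted p = 0.00899). Nfkbie, an inhibitor, and Bcl3, a nuclear cofactor of p52, rose by 1.40 (SE 0.35, adjusted p = 0.0440) and 1.08 (SE 0.22, adjusted p = 0.0220), and both missed the threshold without wild-type replicate 2 or 3. Nfkbie also missed it without ε/ε replicate 1 or 2 or γ1/γ1 replicate 2 or 3 (adjusted p up to 0.166), and Bcl3 without ε/ε replicate 3 (up to 0.0854).

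Heat shock and unfolded protein response genes, which code for chaperones of the cytosol and of the endoplasmic reticulum, were also higher. Of 17 heat shock and stress genes 3 rose and 0 fell over all genes, and 9 rose adjusted over the list alone, with a median of 0.54 (camera adjusted p = 1.66e-05, adjusted p = 0.496 with an estimated correlation, range 3.96e-07 to 0.496). Hspb1, a small heat shock protein, rose from 3.14 to 4.71 (SE 0.23, adjusted p = 0.00558) and Dnajb1, a co-chaperone of Hsp70, by 1.36 (SE 0.24, adjusted p = 0.0126). Hsph1, a relative of Hsp70, rose by 1.28 (SE 0.25, adjusted p = 0.0184), and Hspb1 rose by 1.03 with the mean of probe sets. Without ε/ε replicate 3 the heat shock difference was 0.83 (camera adjusted p = 3.96e-07). The heat shock median was 1.01, 0.62 and 0.65 in ε/ε replicates 1, 2 and 3, the highest again in the array with the highest macrophage genes. Of 27 unfolded protein response genes 3 rose and 0 fell, 7 rose adjusted over the list alone, and the median was 0.20 (camera adjusted p = 0.00547, adjusted p = 0.496 with an estimated correlation, range 0.000832 to 0.496), and 0.32 without wild-type replicate 1 (adjusted p = 0.00430) and 0.34 under quantile normalization (0.000832). Ppp1r15a, which restores translation after stress, rose by 1.96 (SE 0.28, adjusted p = 0.00552), Dnajb9, a co-chaperone of the endoplasmic reticulum, by 1.31 (adjusted p = 0.0134), and Syvn1, a ligase that marks misfolded proteins, by 1.00 (adjusted p = 0.0288). Dnajb9 and Syvn1 missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0664 and 0.118), Syvn1 also without ε/ε replicate 2 or 3, Dnajb1 without wild-type replicate 3 (0.0586), and Hsph1 without wild-type replicate 1 or 2 (up to 0.0804).

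Markers of marginal zone B cells, the other mature B cell subset of the spleen, were higher in ε/ε cells. Of 28 tested, 11 rose and 1 fell over all genes, and 12 rose and 1 fell adjusted over the list alone, with a median of 0.43 (camera adjusted p = 8.48e-07, adjusted p = 0.0638 with an estimated correlation, range 1.00e-08 to 0.0638). Besides Il9r, Ackr3, a scavenging receptor for chemokines, rose by 2.28 (SE 0.23, adjusted p = 0.00127) from 4.47 ± 0.19 to 6.75 ± 0.31, and Myof, a membrane repair protein, from 3.56 to 5.24 (SE 0.22, adjusted p = 0.00378). Ptpn14, a tyrosine phosphatase, rose by 1.24 (SE 0.20, adjusted p = 0.00936). Of 21 follicular B cell markers 0 rose and 3 fell over all genes, 4 fell adjusted over the list alone, and the list as a whole was not called, with a median of -0.04 (camera adjusted p = 0.855). Besides Zfp318, Cd200, an inhibitory surface ligand, fell by 1.38 (SE 0.24, adjusted p = 0.0119) and Cd55, which protects cells from complement, fell by 0.95 (SE 0.17, adjusted p = 0.0136). Ptpn14 missed the threshold without wild-type replicate 2 (adjusted p = 0.0504), and Cd55 without wild-type replicate 2 or 3 (up to 0.0656).

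Among 19 genes of survival and apoptosis 0 rose and 2 fell, 3 fell adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.578), or 0.066 without ε/ε replicate 1 (adjusted p = 0.955, range 0.181 to 0.989). The second of these was Mcl1, a relative of Bcl2 that also blocks apoptosis, which fell by 0.87 (SE 0.14, adjusted p = 0.00753), or by 0.48 with the mean of probe sets. Of 30 genes of the B cell receptor and its positive signalling chain 2 rose and 0 fell, 4 rose and 1 fell adjusted over the list alone, and the median was 0.07 (camera adjusted p = 0.479), or 0.0058 and 0.12 without wild-type replicates 3 and 1. They were Blnk, the scaffold of the signalling complex, by 0.79 (SE 0.15, adjusted p = 0.0156), and Syk, the kinase that binds the signalling chains, by 0.73 (SE 0.17, adjusted p = 0.0377). Of 32 inhibitors of receptor signalling 2 rose and 0 fell, 4 rose and 6 fell adjusted over the list alone, and the median was 0.03 (camera adjusted p = 0.697). Lilrb4a and Siglecg, both inhibitory receptors, rose by 1.98 (SE 0.51, adjusted p = 0.0494) and 0.60 (SE 0.13, adjusted p = 0.0294). Blnk, Syk and Siglecg missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0705, 0.128 and 0.109). Syk and Siglecg also missed it without ε/ε replicate 2 or 3, Syk without ε/ε replicate 1 or γ1/γ1 replicate 2 or 3, and Lilrb4a without any of the arrays but wild-type replicate 3 (up to 0.140).

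Genes of oxidative phosphorylation, the respiratory chain of mitochondria, were lower as a group, while 54 of the 56 tested did not pass alone. Their median was -0.32 (camera adjusted p = 0.000328, adjusted p = 0.496 with an estimated correlation, range 2.15e-05 to 0.496), and 2 fell both over all genes and adjusted over the list alone. Under quantile normalization the median was -0.16 (adjusted p = 0.00284). Ndufs1, of complex I, fell by 0.71 (SE 0.14, adjusted p = 0.0183) and Atp5l, of the ATP synthase, fell by 0.64 (SE 0.15, adjusted p = 0.0301), and both missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0804 and 0.113), Atp5l also without wild-type replicate 1 or any ε/ε array. Markers of macrophages and monocytes had a median of 0.95 over 18 genes (camera adjusted p = 9.03e-05, adjusted p = 0.496 with an estimated correlation, range 8.58e-08 to 0.496). Of these 0 passed in limma over all genes and 5 rose adjusted over the list alone, with C1qb, a complement protein of macrophages, at 2.39 (SE 0.62, adjusted p = 0.0505) and C1qa at 1.22 (SE 0.32, adjusted p = 0.0509). C1qb passed without ε/ε replicate 1 (adjusted p = 0.0367) or 3 (0.0160), in a range of 0.0160 to 0.153 over the alternatives, and C1qa without ε/ε replicate 2 (0.0499) or 3 (0.0474), in a range of 0.0347 to 0.181. Both also passed with arrays centred on their medians, the mean of probe sets, trend and robust fitting, array weights, the replicate block and protein-coding genes alone, C1qb with the 7 arrays of high Xist too. The list median was 2.16 in ε/ε replicate 1, 0.49 in replicate 2 and 0.19 in replicate 3, and without replicate 1 the difference was 0.34 (camera adjusted p = 0.00672), against 0.55 with the covariate for low Xist (0.00173). In all, 7 of 31 lists passed, 6 up and 1 down. With an estimated correlation 0 passed, the smallest adjusted p being 0.0638, and the fry test called 1, the marginal zone list.

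**Figure D2:**
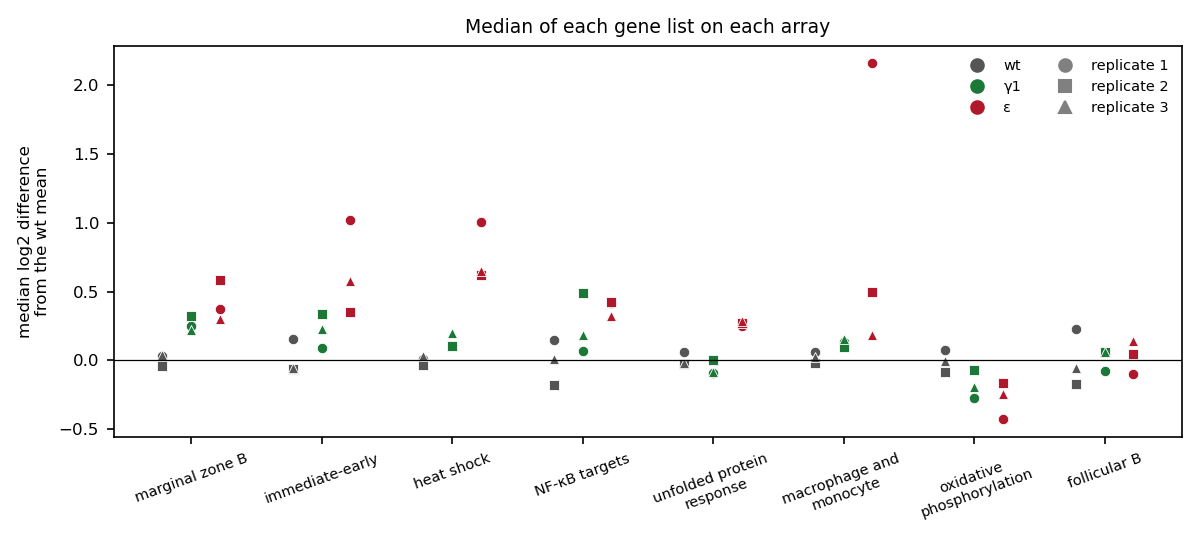
Median log2 difference of 8 gene lists from the wild-type mean, 1 point per array and 3 arrays per genotype. The macrophage list stood at 2.16 in ε/ε replicate 1 and at or below 0.49 on the other 8 arrays, while the heat shock list lay between 0.62 and 1.01 in ε/ε cells.

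In γ1/γ1 cells, set against wild-type to ask what the γ1 allele changes, few genes passed. Il9r rose by 2.98 (SE 0.30, adjusted p = 0.0122) from 5.84 ± 0.63 to 8.81 ± 0.25 (SD, n = 3), or 7.87-fold. Cacna1e rose by 1.62 (SE 0.17, adjusted p = 0.0122) to 5.87 ± 0.24, or 3.08-fold. St8sia6, an enzyme that adds sialic acid to glycans, rose by 1.53 (SE 0.17, adjusted p = 0.0122) from 5.19 ± 0.18 to 6.72 ± 0.19. The transcript 4930597A21Rik fell from 5.10 to 3.32 (SE 0.21, adjusted p = 0.0196), and the fifth gene to pass was Ighm at its brightest probe set.

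These 5 genes, 3 higher and 2 lower, all differed at least 2-fold, and 830 had an unadjusted p under 0.05. With only the 6 arrays compared, limma called 0 genes, so 0 of the 5, with 974 at an unadjusted p under 0.05. In 12.4% of all genes the 3 arrays of 1 genotype lay above those of the other, against 10% by chance, and in each of the 5. Without γ1/γ1 replicate 2 limma called 0 genes (1016 at an unadjusted p under 0.05). Without γ1/γ1 replicate 3 it called 3, all among the 5, without wild-type replicate 2 it called 2, both among the 5, and without wild-type replicate 3 it called 2, 1 of them among the 5. With only the 7 arrays of high Xist it called 3, of which Ighm alone was among the 5. Each of the 5 missed the threshold without at least 1 array, with adjusted p over the alternatives of 0.00619 to 0.0855 for St8sia6, 0.00692 to 0.183 for 4930597A21Rik and 0.00692 to 0.196 for Ighm. Il9r had an adjusted p between 0.00458 and 0.0855 over the alternatives, with changes of 2.62 to 3.20, and Cacna1e the same range of adjusted p, with changes of 1.49 to 1.73. Among the 20 genes with the smallest p, Traf1 differed by 1.37 (adjusted p = 0.0957), Clec4g, a lectin gene, by -2.05 (adjusted p = 0.107), Lilrb4a by 3.02 (adjusted p = 0.154) and Ptpn14 by 1.14 (adjusted p = 0.184). Traf1 passed without γ1/γ1 replicate 1 (adjusted p = 0.0172, range over the alternatives 0.0129 to 0.401) and Clec4g without ε/ε replicate 1 (0.0179, range 0.0104 to 0.402). Both also passed with array weights and with the 7 arrays of high Xist, Traf1 with centred arrays and the covariate for low Xist too. The others were Rnu3a, Cyp2r1, Jhy, Cpne4, 6430590A07Rik, Rras2, Tmem108, Rpph1, Rogdi, Ints4 and Gm5781, with differences between -2.16 and 1.47. Of these Jhy passed without ε/ε replicate 3 (adjusted p = 0.0358, range 0.0358 to 0.720) and Rpph1 without wild-type replicate 1 (0.0176, range 0.0176 to 0.789).

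Marginal zone markers were higher as a group in γ1/γ1 cells too. Of 28 tested, 1 rose, Il9r, and 5 rose and 1 fell adjusted over the list alone, with a median of 0.21 (camera adjusted p = 8.54e-05, adjusted p = 0.132 with an estimated correlation, range 3.82e-05 to 0.132), or 0.11 under the stricter filter (3.82e-05). Of 24 NF-κB targets 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.000748, adjusted p = 0.441 with an estimated correlation, range 3.82e-05 to 0.441). Its members with the smallest p were Traf1 and Nfkb2, the latter at 0.81 (adjusted p = 0.498), and without γ1/γ1 replicate 2 the list's median was 0.10 (adjusted p = 0.0640), and without wild-type replicate 2 it was 0.16 (adjusted p = 0.00630). Of 29 immediate-early genes 0 passed, alone or over all genes, with a median of 0.21 (camera adjusted p = 0.0355, adjusted p = 0.651 with an estimated correlation, range 0.00108 to 0.745). Dusp1 differed by 0.64 (adjusted p = 0.686) and Jun by 0.83 (adjusted p = 0.725). The immediate-early call was lost without γ1/γ1 replicate 2 (median 0.0072, adjusted p = 0.265), γ1/γ1 replicate 3 (0.0633), wild-type replicate 2 (0.0556) or wild-type replicate 3 (0.134), with no filter (0.0655) and with the covariate for low Xist (0.142).

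The list named after ribosome biogenesis, which also holds genes of other roles, and that of oxidative phosphorylation were lower as groups in γ1/γ1 cells. Of either, 0 genes passed in limma over all genes or adjusted over the list alone. Over the 32 genes of the ribosome biogenesis list the median was -0.24 (camera adjusted p = 0.00221, adjusted p = 0.441 with an estimated correlation, range 0.000128 to 0.441), or -0.13 without γ1/γ1 replicate 1 (adjusted p = 0.0328) and -0.14 with the covariate for low Xist (0.0156), with Tfrc, the transferrin receptor, at -0.40 (adjusted p = 0.698) and Cad, an enzyme of pyrimidine synthesis, at -0.37 (adjusted p = 0.709). Over 56 oxidative phosphorylation genes it was -0.20 (camera adjusted p = 0.00315, adjusted p = 0.651 with an estimated correlation, range 0.000128 to 0.651), with Ndufa9 at -0.73 (adjusted p = 0.454) and Cycs, cytochrome c, at -0.68 (adjusted p = 0.649). The oxidative phosphorylation median was -0.13 without γ1/γ1 replicate 1 (adjusted p = 0.00863) and under quantile normalization, and -0.098 with the covariate for low Xist (0.0373). Its call was lost without γ1/γ1 replicate 3 (median -0.11, adjusted p = 0.0633) and under the stricter filter (adjusted p = 0.0834). Of 30 genes of the receptor's positive signalling chain 0 passed in limma, with Fyn at -0.51 (adjusted p = 0.515) and Cr2 at 0.41 (adjusted p = 0.524). That list had no settled sign, with a median of 0.0032 and a mean of -0.0044, and camera read it as up (adjusted p = 0.982) and fry as down (adjusted p = 0.932). In all, 5 lists passed, 3 up and 2 down, against 0 with an estimated correlation (smallest adjusted p 0.132) and 0 by fry.

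The direct contrast of ε/ε with γ1/γ1 cells asks what separates the isotypes. Bcl2 was lower in ε/ε by 1.87 (SE 0.18, adjusted p = 0.00169, 3.66-fold), at 6.06 ± 0.36 against 7.93 ± 0.06 (SD, n = 3). Zfp318 was lower by 1.57 (SE 0.20, adjusted p = 0.00550) and Cd55 by 1.12 (SE 0.17, adjusted p = 0.0109). Ackr3 was higher by 2.03 (SE 0.23, adjusted p = 0.00360, 4.08-fold), and Klf4, a zinc finger transcription factor of quiescence, was at 4.73 against 3.51 (SE 0.17, adjusted p = 0.00707). Cfp, the complement regulator properdin, was higher by 2.45 (SE 0.38, adjusted p = 0.0121), and Chil5, a chitinase-like gene, was lower by 2.30 (SE 0.22, adjusted p = 0.00178).

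In limma 324 genes passed between ε/ε and γ1/γ1, 124 higher and 200 lower in ε/ε, 173 of them at least 2-fold (75 higher, 98 lower), and 2417 had an unadjusted p under 0.05. The arrays of the genotypes did not overlap for any of the 324 and for 21.1% of all genes, against 10% by chance. Under quantile normalization 380 passed, 203 higher and 177 lower. The share of higher calls was 53.4% in place of 38.3%. The count was 196 without ε/ε replicate 1, 140, 160 and 122 without γ1/γ1 replicates 1, 2 and 3, and 203, 213 and 167 without wild-type replicates 1, 2 and 3. With a covariate for the arrays of low Xist 513 genes passed, with only the 7 arrays of high Xist 88, and with the 6 arrays compared 56. Of the 33 named genes that passed, 24 passed with each array left out, among them Bcl2, Zfp318, Cd55, Ackr3, Klf4, Cfp and Chil5. With the 6 arrays 17 of the 33 missed the threshold, Cd55, Cfp, Cd36, Cebpb, Hes1 and Ighm among them, and with the 7 arrays of high Xist 15, again with Cd55, Cfp, Cebpb and Hes1. The named genes that missed the threshold numbered 8, 1 and 3 without ε/ε replicates 1, 2 and 3, 8, 5 and 8 without γ1/γ1 replicates 1, 2 and 3, and 2, 3 and 4 without wild-type replicates 1, 2 and 3. Small RNAs and olfactory receptor genes were again among the extremes, with Olfr310 at 8.95 in ε/ε against 5.12 in γ1/γ1, Mir466b-2 at 7.60 against 3.78, Mir297a-4 at 8.36 against 4.72 and Mir466h at 10.84 against 7.96. Mir505 read 2.90 in ε/ε against 7.60 in γ1/γ1, and Cldn34b3 read 2.34 against 5.66. The other genes at the extremes were Mir669h, Mir669m-1, Gm15128, Rgs1 and Gm13271, higher in ε/ε with means of 5.05 to 7.62, 3 of them from γ1/γ1 means below the array medians, and Adam6b, Olfr1219, Olfr875, Mir1927, Mir103-2, Mir5104 and Dennd5b, with means of 2.44 to 6.22 in ε/ε against 5.39 to 8.78 in γ1/γ1. Mir669h missed the threshold without ε/ε replicate 1 or 3, any γ1/γ1 array or wild-type replicate 3 (adjusted p up to 0.0896). Mir5104 missed it without ε/ε replicate 1 or 3, γ1/γ1 replicate 1 or 2 or wild-type replicate 2 or 3 (up to 0.0860), and its difference with the 7 arrays of high Xist was -1.59 in place of -2.40. Mir103-2 missed it without ε/ε replicate 1 or any γ1/γ1 array (up to 0.0753), and Rgs1 without γ1/γ1 replicate 1 or 3 (up to 0.0662).

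Unfolded protein response genes were higher as a group in ε/ε than in γ1/γ1 cells. Of 27 tested, 1 was higher over all genes, Ppp1r15a by 1.62 (SE 0.28, adjusted p = 0.0172), and 11 were higher and 1 lower adjusted over the list alone, with a median of 0.38 (camera adjusted p = 2.33e-05, adjusted p = 0.425 with an estimated correlation, range 1.52e-06 to 0.425). Of 29 immediate-early genes 2 were higher, Klf4 and Junb, the latter by 1.51 (SE 0.34, adjusted p = 0.0489), and 9 were higher adjusted over the list alone, with a median of 0.46 (camera adjusted p = 2.33e-05, adjusted p = 0.449 with an estimated correlation, range 1.52e-06 to 0.449), or 0.20 with the 7 arrays of high Xist (0.0123). Of 17 heat shock and stress genes 2 were higher, Hsph1 by 1.35 (SE 0.25, adjusted p = 0.0253) and Hspb1 at 4.71 against 3.55 (SE 0.23, adjusted p = 0.0302), and 4 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.000556, adjusted p = 0.449 with an estimated correlation, range 7.42e-06 to 0.449). The heat shock median was 0.19 without γ1/γ1 replicate 3 (adjusted p = 0.00963) and 0.32 with the 7 arrays of high Xist (0.0120), and Hspb1 missed the threshold at 0.71 with the mean of probe sets (0.0753). Macrophage markers had a median of 0.94 (camera adjusted p = 0.000600, adjusted p = 0.609 with an estimated correlation, range 3.65e-07 to 0.609), with Lyz2, a lysozyme gene, at 1.10 (adjusted p = 0.0718) and C1qb at 2.34 (adjusted p = 0.0745). Lyz2 passed without ε/ε replicate 2 (adjusted p = 0.0273, range 0.0273 to 0.292) and C1qb without ε/ε replicate 3 (0.0267, range 0.0267 to 0.192) or with the covariate for low Xist (0.0336). Of the 18 tested 0 passed in limma over all genes and 4 were higher adjusted over the list alone, and without ε/ε replicate 1 the median was 0.27 (camera adjusted p = 0.0940). The macrophage call was also lost under the stricter filter (adjusted p = 0.163) and with the 7 arrays of high Xist (median 0.17, 0.0944). Junb missed the threshold without any of the arrays but ε/ε replicate 2 (adjusted p up to 0.138), Hspb1 without any but ε/ε replicate 3 and γ1/γ1 replicate 2 (up to 0.0968), and Ppp1r15a and Hsph1 without ε/ε replicate 1 or γ1/γ1 replicate 1 or 3 (up to 0.0671 and 0.0878).

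Marginal zone markers were higher in ε/ε than in γ1/γ1 cells as well. Of 28 tested, 6 were higher and 1 lower, and 8 were higher and 1 lower adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0146, adjusted p = 0.425 with an estimated correlation, range 0.00161 to 0.425). Besides Ackr3 these included Cd36, a scavenger receptor, by 1.76 (SE 0.25, adjusted p = 0.00879), Cebpb, a transcription factor, at 4.94 against 3.62 (SE 0.23, adjusted p = 0.0177), and Hes1, a target of Notch signalling, by 1.06 (SE 0.16, adjusted p = 0.0104). The median was 0.22 without ε/ε replicate 3 (adjusted p = 0.0102) and 0.081 without γ1/γ1 replicate 1 (adjusted p = 0.0313), and 0.26 under the stricter filter (0.0176). Without ε/ε replicate 2 the list's adjusted p was 0.0561, and Cebpb missed the threshold without ε/ε replicate 1 or γ1/γ1 replicate 2 or 3 (up to 0.0689). Markers of immature and transitional B cells had a median of 0.35 over 17 genes, 0 of which passed in limma alone or over all genes (camera adjusted p = 0.0311, adjusted p = 0.623 with an estimated correlation, range 0.000249 to 0.623), with Bcl7a at 0.96 (adjusted p = 0.103, and 0.0293 without ε/ε replicate 1 and 0.0342 with the covariate for low Xist, in a range of 0.0293 to 0.243) and Lrrk1 at 0.74 (adjusted p = 0.152). That call was lost without ε/ε replicate 2 (adjusted p = 0.0978), ε/ε replicate 3 (0.227) or γ1/γ1 replicate 1 (0.148), and under the stricter filter (0.139), and the median was 0.52 without γ1/γ1 replicate 2 (0.0147). Of 21 follicular markers 0 were higher and 2 lower, Zfp318 and Cd55, over all genes and adjusted over the list alone, and of 19 survival genes 0 were higher and 1 lower, Bcl2. The follicular list had a median of 0.00043 and a mean of -0.13 (camera adjusted p = 0.428, direction down), and the survival list had a median of -0.06 (camera adjusted p = 0.339), or 0.033 without ε/ε replicate 1 (0.565, range 0.195 to 0.854). In all, 6 lists passed, all up, against 0 with an estimated correlation (smallest adjusted p 0.425), while fry called 4, the unfolded protein response and marginal zone lists up and the lists of small nucleolar RNAs and memory B cell markers down, each with an adjusted p of 0.0453.

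The contrasts of ε/ε and of γ1/γ1 with wild-type overlapped in Cacna1e and Il9r, higher in both, and in 4930597A21Rik, lower in both. Independent lists would share 0.0698 and 0.0804 genes. None of these genes passed between γ1/γ1 and wild-type with the 6 arrays compared or with the 7 arrays of high Xist. With the covariate for low Xist, Cacna1e and Il9r passed there and 4930597A21Rik did not. Of the 772 genes that passed between ε/ε and wild-type, the γ1/γ1 mean lay between the other two means for 643. The median ratio of the γ1/γ1 change to the ε/ε change was 0.238. The genes were chosen on the ε/ε change and both changes share the wild-type arrays, which raises these values without any γ1/γ1 effect. With γ1/γ1 simulated as unchanged from wild-type and the ε/ε changes of all genes kept as measured, the γ1/γ1 mean lay between for 61.2% to 66.7% of called genes in 100 draws, against 83.3% here, and the ratio was 0.0707 to 0.0995. Keeping only the changes of the called genes gave lower values. The simulation draws genes independently and with the same variance in each genotype, which the arrays do not. It also leaves out other differences that both mutant genotypes share against wild-type, such as an array of low Xist in each. Of the 772, 249 also passed between ε/ε and γ1/γ1 in the same direction, 93 higher and 156 lower in ε/ε, against 2.88 and 8.04 for independent lists, and these contrasts share the ε/ε arrays.

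Across the 12170 genes the log2 changes in ε/ε and γ1/γ1 cells against wild-type had Pearson's r of 0.457, where genes are not independent replicates. Unchanged groups simulated against the same wild-type arrays gave 0.501 on average (0.472 to 0.533 in 100 draws). The covariance was 0.0588 against a simulated 0.0294 (0.0268 to 0.0329), a difference of 0.0293. The signs were the same for 66.4% of genes, against a simulated 66.7% (65.4% to 67.9%). The simulated values include the shared controls. The simulation draws genes independently, so its ranges are too narrow. It also gives the genotypes the same variance per gene, while r was 0.970 to 0.978 among wild-type arrays and 0.929 to 0.958 among ε/ε arrays. A smaller wild-type variance would lower the simulated r and covariance. That could bring the simulated r nearer to the observed one, but it would widen the excess of the covariance. Other differences that both mutant genotypes share against wild-type, such as an array of low Xist in each, were not simulated. No genotype effect is therefore read from either value. With 3 wild-type arrays the controls could not be split into sets of at least 2 arrays each, so part of the excess of the overlap counts may come from the shared controls.

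**Figure D3:**
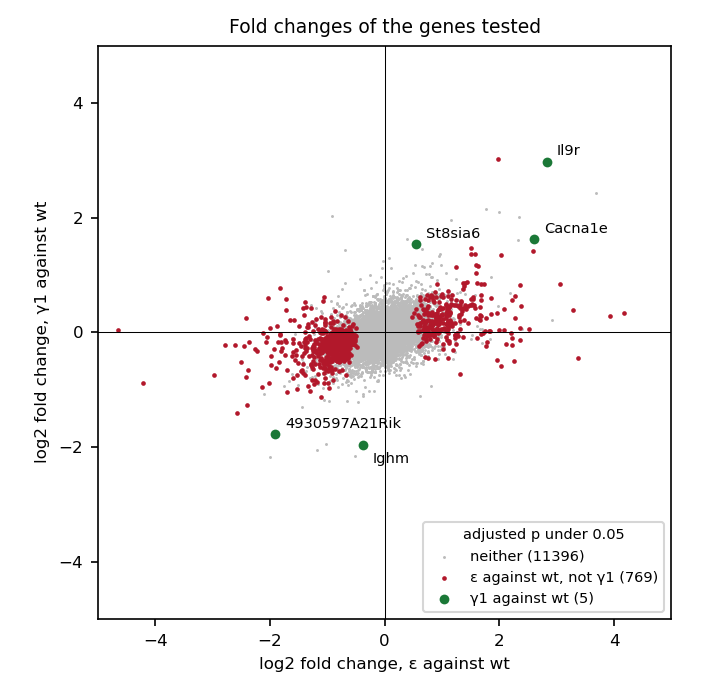
Log2 change in ε/ε against wild-type (horizontal) and in γ1/γ1 against wild-type (vertical) for each of the 12170 genes tested, coloured by the contrast in which a gene passed, with the 5 genes that passed in γ1/γ1 labelled. Il9r lies at 2.82 and 2.98 and Cacna1e at 2.60 and 1.62.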

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

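The tests of probe sets without a single gene name were chosen after the data had been seen. The comparisons of the report rest on probe sets with 1 gene symbol and leave out the other 17824. Fitted with limma over all 41345 probe sets, 695 of the 17824 differed between ε/ε and wild-type cells at an adjusted p under 0.05, 21 between γ1/γ1 and wild-type, and 510 between ε/ε and γ1/γ1. These are shares of 3.90%, 0.118% and 2.86%. The shares among the 23521 probe sets with 1 symbol, in the same fits, were 2.08% (489 probe sets), 0.0255% (6) and 0.999% (235). For 1814 of the 17824 the annotation gives several gene symbols, and which of these was measured is not settled. What the other 16010 measure is not given in the sources used here.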

How the results depend on the processing

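The fits with a covariate for low Xist, with the 7 arrays of high Xist and with protein-coding genes were chosen after the data had been seen. Of the genes named in the text that passed, 27 of 54 kept their call and direction under all alternatives between ε/ε and wild-type, 0 of 5 between γ1/γ1 and wild-type, and 13 of 33 between ε/ε and γ1/γ1. The called lists kept their direction under all alternatives, and the 7 called lists of ε/ε against wild-type lost their calls only under the other list tests. The cause was not tested for any change below unless one is given.

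Between ε/ε and wild-type 772 genes passed. The count was 347 at an absolute log2 fold change of at least 1 and 1626 at an adjusted p under 0.1, which follow from the thresholds, 424 with the 6 arrays compared, where fewer arrays set the variance, and 186 to 789 with 1 array left out. Between γ1/γ1 and wild-type, 5 genes passed, against 3 with the 7 arrays of high Xist, 3 among protein-coding genes and 0 to 6 with 1 array left out. Limma called 0 genes there with the 6 arrays (974 at an unadjusted p under 0.05). Between ε/ε and γ1/γ1, 324 genes passed, against 173 at an absolute log2 fold change of at least 1, 803 at an adjusted p under 0.1, 56 with the 6 arrays, 513 with the covariate for low Xist, 88 with the 7 arrays and 122 to 330 with 1 array left out. The F test's 500 genes became 190 with the 7 arrays and 173 to 399 with 1 array left out. The correlation of 0.457 ranged from 0.395 to 0.551 with 1 array left out.

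Camera with an estimated correlation called 0 lists in each of the 3 comparisons, where the preset correlation called 7, 5 and 6. Fry called 1 list for ε/ε against wild-type and 0 for γ1/γ1 against wild-type. With 1 array left out 3 to 7 lists passed for γ1/γ1 against wild-type.

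Directions turned only in results that had not passed, except for Ighm between ε/ε and γ1/γ1, where the mean of the 7 probe sets gave -0.27 because they disagree. The follicular list of ε/ε against wild-type, at -0.04, was 0.022 under the stricter filter, 0.081 with the covariate for low Xist, and -0.0065 with the 7 arrays of high Xist, where camera read it as up, and it ran from -0.082 to 0.12 with 1 array left out. The survival list ran from -0.20 to 0.066 over the alternatives for ε/ε against wild-type and from -0.27 to 0.033 for ε/ε against γ1/γ1, turning in both without ε/ε replicate 1 and under quantile normalization (0.023 and 0.0053), and in the former with the 7 arrays of high Xist. Over the alternatives the lists of receptor inhibitors (-0.0063 without ε/ε replicate 3, up to 0.085) and antigen presentation (-0.0079 without wild-type replicate 2, up to 0.21) for ε/ε against wild-type, and the follicular list for ε/ε against γ1/γ1 (-0.10 to 0.036), also crossed 0. Medians of lists that were not called moved by over 1.5 times in others without a turn: receptor signalling ran from 0.0058 to 0.20 and plasma cells from 0.043 to 0.19 for ε/ε against wild-type, and immature and transitional markers from 0.12 to 0.42. The list of positive receptor signalling for γ1/γ1 against wild-type had a median of 0.0032, which fry read as down, of 0.0031 with no filter, and of -0.084 to 0.074 with 1 array left out. Between γ1/γ1 and wild-type, Cd79a ran from -0.057 to 0.56 and Cd79b from -0.021 to 0.14.

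The labels give the replicate numbers no meaning, and same-numbered arrays did not all deviate together by the bound set for pairing, an r over 0.1 in every pair. Same-numbered arrays deviated from their group means with r of -0.04 to 0.01 between ε/ε and wild-type, -0.09 to 0.03 between γ1/γ1 and wild-type and 0.05 to 0.16 between ε/ε and γ1/γ1, and 2, 2 and 6 of 6 arrays correlated best with their own number. The 6 of 6 between ε/ε and γ1/γ1, whose replicate 1 arrays also share low Xist, are a hint from the data that those numbers may mark something shared. With the replicate block 668, 0 and 237 genes passed in limma, with 846 at an unadjusted p under 0.05 beside the 0.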

Other observations

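The tests of macrophage RNA in ε/ε replicate 1, of macrophage RNA behind the immediate-early genes in its present choice of genes, of handling stress and of marginal zone B cells in the sort, the comparison of gene kinds and the counts of Sfmbt2 microRNAs and of olfactory receptor genes were chosen only after the result was seen. MicroRNA genes passed more often than protein-coding genes in ε/ε cells. Of 163 tested, 40 differed between ε/ε and wild-type (24.5%), against 658 of 11038 protein-coding genes (5.96%, two-sided Fisher's exact test, adjusted p = 1.27e-13), and 29 (17.8%) against 259 (2.35%) between ε/ε and γ1/γ1 (adjusted p = 9.16e-16). Limma called 0 of the 163 between γ1/γ1 and wild-type. Genes are not independent, and many of these microRNAs have near-identical copies, so the p-values overstate the evidence. Of 12 tested microRNA genes that lie inside Sfmbt2, a host gene of a large microRNA cluster, 8 were higher and 3 lower in ε/ε than in wild-type cells. Sfmbt2 itself was not among the genes tested, so whether the host transcript changed is not known. Of 140 olfactory and vomeronasal receptor genes 9 were higher and 14 lower, while 6.34% of all genes tested passed. Whether these signals reflect transcripts of the cells or effects of the probe sets or the amplification was not tested.

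Markers of immature and transitional B cells, antigen presentation and plasma cells were not called as lists between ε/ε and wild-type. Spib, a transcription factor of the B lineage, rose by 1.54 (SE 0.33, adjusted p = 0.0253) and Bcl7a by 1.15 (SE 0.29, adjusted p = 0.0426), the 2 of 17 immature and transitional markers that passed. Both missed the threshold without ε/ε replicate 2 or 3 or wild-type replicate 2 or 3 (adjusted p up to 0.104 and 0.161), and Bcl7a also without wild-type replicate 1 or γ1/γ1 replicate 2 or 3. That list had a median of 0.24 (camera adjusted p = 0.0854), which became 0.42 without ε/ε replicate 1 (adjusted p = 0.00131, range over the alternatives 0.000664 to 0.733), and the list also passed with no filter, with the mean of probe sets, with array weights and with either setting for Xist. Adjusted over the list alone, 2 rose and 1 fell. Tapbp, which loads peptides on class I molecules, and H2-K1, a class I molecule, rose by 1.13 (adjusted p = 0.0183) and 0.62 (adjusted p = 0.0200) among 22 antigen presentation genes, in a list with a median of 0.08 (camera adjusted p = 0.258), also 2 adjusted over the list alone. Both missed the threshold without wild-type replicate 2 or 3 (adjusted p up to 0.0622 and 0.0822), and Tapbp without ε/ε replicate 1. Of 23 plasma cell genes Pou2af1, a B cell coactivator, rose by 1.62 (SE 0.27, adjusted p = 0.00976) and Spcs2, of the signal peptidase, fell by 0.76 (SE 0.18, adjusted p = 0.0348), with a median of 0.07 (camera adjusted p = 0.479), or 0.16 and 0.14 without ε/ε replicates 1 and 2, and 2 higher and 1 lower adjusted over the list alone. Spcs2 missed the threshold without ε/ε replicate 1 or 3, γ1/γ1 replicate 2 or any wild-type array (adjusted p up to 0.115).

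The 6 arrays of each contrast can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For ε/ε and wild-type 1 split, the real one, gave 772 genes, and the highest of the others gave 0. For γ1/γ1 and wild-type 1 split gave 5 genes, and the highest other gave 0. For ε/ε and γ1/γ1 1 split gave 324 genes, and the highest other gave 0. The 9 arrays can be split into 3 groups of 3 in 280 ways, of which 100 were drawn with the real one included. Of these, 1 gave as many genes in the F test as the real 500, and the highest other gave 3. Such a count was thus rare among the splits drawn. Splits that mix the genotypes also raise the spread within groups, which lowers their counts. The splits cannot separate genotype from anything else that differs between the groups.

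Macrophage genes stood high in ε/ε replicate 1, with a list median of 2.16 over the wild-type means against -0.02 to 0.49 on the other 8 arrays. In ε/ε replicates 1, 2 and 3, C1qb read 8.29, 6.13 and 5.09, Spic 8.11, 5.39 and 5.0, Vcam1 8.01, 5.14 and 3.76 and Hmox1 9.07, 6.09 and 4.93, genes of red pulp macrophages named after their values were seen. Those genes prompted the candidate explanation of macrophage RNA in that sample, so they do not test it, and 12 macrophage genes on none of the lists do. Their median there was 1.05, against -0.11 to 0.29 on the other 8 arrays, as that explanation needs. Of the 12, 8 were highest in ε/ε replicate 1, while Slc11a1, Lipa, Tlr4 and Cd209b were not. A sort for follicular B cells would, however, remove macrophages, and the labels do not give the gates. Expression of these genes by the ε/ε B cells themselves was not tested and stays open.

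The immediate-early genes that rose in ε/ε cells may follow from macrophage RNA, from handling of the cells or from signals of the receptor. Macrophage RNA as the whole cause is argued against for 16 immediate-early genes as a set. They were raised by at least 1 on the log2 scale in replicate 1, a rule applied to both lists alike. Of the 16, 9 rose in limma between ε/ε and wild-type, so the set also holds genes that did not pass. The share of the replicate 1 excess over wild-type seen in replicates 2 and 3 had a median of 0.440 (quartiles 0.228 to 0.662). For 14 macrophage genes it was 0.0552 (quartiles 0.0133 to 0.126), with a two-sided permutation p of 0.000620 over 100000 resamples. Genes measured on the same arrays are not independent, so this p overstates the evidence. Macrophage genes also drew attention by standing high in replicate 1, which favours a low share. Nr4a1, Ccl4 and Egr1 had shares of at most 0.0992, within the macrophage quartiles, and for them macrophage RNA stays open. The others of the set lay above those quartiles. Handling stress stays open, since the 17 heat shock genes, 0 of which are on the immediate-early list, had a median difference of 0.54 (SD 1.15). A signal from the ε receptor is a hypothesis that the design names and that was not tested.

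Of 28 marginal zone markers 11 rose in ε/ε cells and 1 fell, in a list not called with an estimated correlation (adjusted p = 0.0638), and the rise may reflect marginal zone B cells in the sort or a change within follicular cells. The surface markers Cr2, Cd1d1 and Cd9 had a median difference of 0.065 (SD 0.19), below the 1.23 of the 11 members that rose. S1pr3, also chosen as a marker, was not among the genes tested. All 3 markers tested read above the array median in wild-type cells. Markers that follicular cells carry themselves would hide a small share of marginal zone cells. For these genes the explanations cannot be told apart, because the labels give neither the gates nor the purity of the sort.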
